A study of Arabidopsis thaliana with 36 samples.

How the data were processed

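Gene expression was measured by RNA sequencing in 36 libraries of Arabidopsis thaliana roots, in 12 groups of 3. Seedlings 7 days old were moved to liquid medium with 75 uM Fe or to Fe-deficient medium with 50 uM of the Fe chelator FerroZine, with or without 100 nM flg22, for 24 h, and each library pooled about 15 roots. The groups come from the labels of the libraries, and every column of the tables matched 1 library. The labels do not state what a replicate number marks, so no replicate term was in the model.

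The authors deposited a table of raw counts per gene locus, made with a pipeline in which STAR 2.7.0a, edgeR 3.36.0 and the genome build TAIR10 are named without their roles; the counter, strand setting and gene filter are not stated. The authors also deposited a normalised signal table in CPM, which was checked to be the count table times 1 constant per column, with scaling factors from 0.970 to 1.05 that match TMM factors on all genes. The CPM table was used for one alternative. The reference at hand is TAIR10.1, which differs from the build the authors name, so it supplied gene symbols only and no positions are given. Among the loci, 4 were mitochondrial and 0 were plastid loci. Sequence reads were not used here.

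Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalisation, filterByExpr at a minimum count of 10, 1 mean per group, and a robust quasi-likelihood F-test over all 36 libraries. TMM factors ran from 0.967 to 1.05. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 20354 genes tested are called changed. There were 19 comparisons, 12 between pairs of groups and 7 differences of differences. CPM values use TMM-scaled library sizes. Where a group held no count of a gene, the fold is a lower bound from a floor of 3 counts over the group. Where a group held 1 to 3 counts, the ratio has a 95% counting interval.

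The 24 gene lists, with 208 genes of which 199 were tested, were written before the data were examined, as were the comparisons, the tests and the alternatives, except where stated. Lists were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. CYP71A12 and CYP71A13 were on a list and were not analysed here. Fe-responsive genes were those called in fls2 under Fe deficiency with at least a 2-fold change, because Fe deficiency in WT shares libraries with the effect of flg22 in Fe-deficient WT.

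Genes were named by a rule: in Fe deficiency in WT, flg22 in WT with or without Fe, and IMA1ox against WT with Fe, the 6 largest changes each way among called genes with non-overlapping groups and a mean of at least 5 CPM in 1 group. Non-overlap arises by chance in 10% of comparisons of 3 with 3 libraries. In other comparisons the 3 largest each way were named. Members of the lists among the 4 largest changes, and a fixed set of genes of Fe uptake and immunity, could also be named, and which of these are given as examples was chosen after their values were seen. The stability of calls was followed for 313 pairs of a gene and a comparison, 288 of them past the test. One gene among them is not reported here.

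Alternatives were RLE size factors, library totals alone, no filter on low counts, a filter at 5 CPM in 3 libraries, DESeq2 1.42.0, limma-trend on the log2 of the CPM table plus 1, a fit of the compared groups alone, replicate number as a block, each library left out in turn, a 2-fold minimum, and other choices of Fe-responsive genes. Values from DESeq2 are rounded to the digits that repeat between runs. Leaving out 2 libraries that stood apart, and leaving the overexpressed IMA1 or the mutated FLS2 out of the gene lists and the Fe-responsive genes, were added after the data were examined. In simulations, edgeR recovered 98.5% of genes changed 2-fold for Fe deficiency in WT, with 2 false calls. A difference of differences gave 94.0% (64.2% at 1.5-fold) and 6 false calls. Real recovery may be lower.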

Results

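RNA sequencing measured gene expression in 36 libraries from roots of Arabidopsis thaliana seedlings, 3 libraries for each of 12 groups. The groups crossed 3 genotypes with 4 treatments. The genotypes were Col-0 wild type (WT), fls2, a mutant of the receptor that perceives bacterial flagellin, and IMA1ox, a line that expresses the small peptide gene IMA1 fused to the fluorescent protein mCitrine from the UBQ10 promoter. The treatments were Fe sufficiency or Fe deficiency, each with or without flg22, the flagellin peptide that FLS2 recognises. Each library was a pool of about 15 roots, so p-values measure the spread between these pools. Library totals ran from 28130600 to 40903400 counts, and the 10 most abundant genes took 4.87% to 7.68% of the counts. Of 24532 genes in the count table, 1161 had no count in any library and 20354 were tested. In the text, values after ± are the standard error for a log2 fold change and the SD for a mean normalised count (CPM, the count scaled to the library size), with n = 3 libraries per group. Adjusted p-values of genes came from the edgeR quasi-likelihood test with the Benjamini-Hochberg method. Those of gene lists came from limma's camera, which compares a list with all other genes. The test named fry, where used, asks if a list's genes move on balance in 1 direction, and its mixed form asks if they change in either direction. Lists past 0.05 with no second p also passed with an estimated correlation. Counting intervals and floors cover counting error only. Where leaving out 1 library moved the fold of a called gene by over 1.5 times, the log2 value without it ends the paragraph. Single libraries are written as genotype, Fe supply (+Fe or -Fe), flg22 where given, and replicate number.

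**Figure D1:**
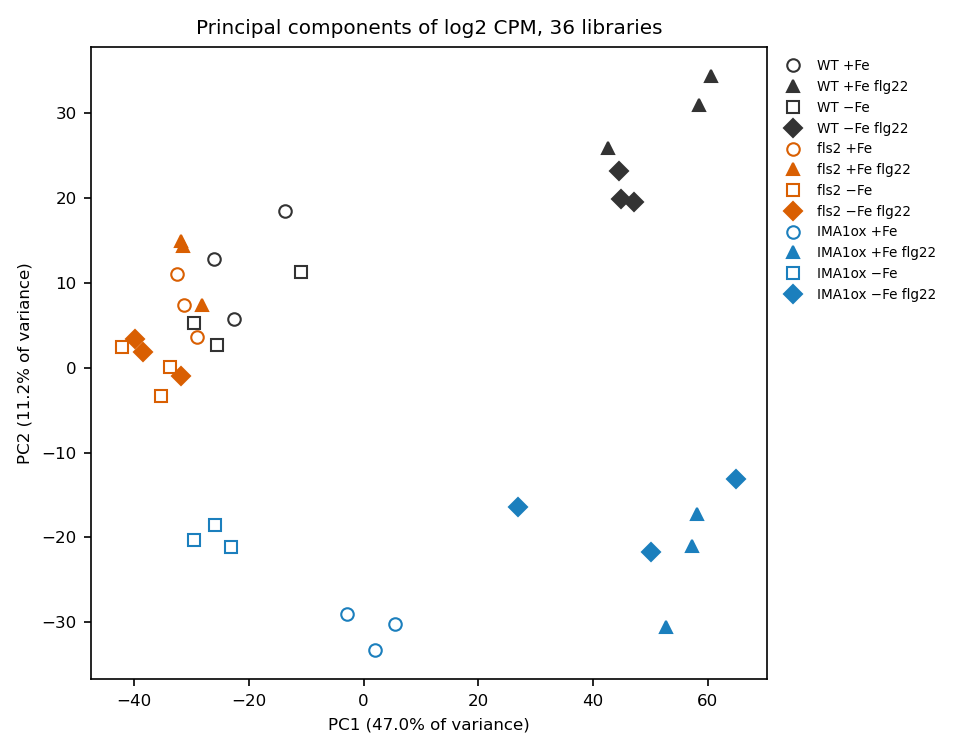
Principal components of the log2 CPM of the tested genes, with 1 point per library, coloured by genotype and shaped by treatment. Component 1 held 47.0% and component 2 held 11.2% of the variance.

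FLS2 (AT5G46330), the flagellin receptor kinase, had no count in the 6 untreated fls2 libraries, and the Fe-sufficient fls2 group lay at least 38.7-fold lower than WT (floor of 3 counts over the group). flg22-treated fls2 libraries held at most 3 counts of it. In WT, FLS2 stood at 1.20 ± 0.403 CPM with Fe and at 5.01 ± 0.749 CPM after flg22. IMA1 (AT1G47400), a small peptide that promotes Fe uptake, reached 341 ± 8.29 CPM in IMA1ox with Fe against 2.45 ± 0.657 CPM in WT, and 310 ± 3.96 against 13.8 ± 4.74 CPM under Fe deficiency. Reads of IMA1 in IMA1ox include the transgene, and IMA1 and IMA2 (AT1G47395) are similar enough in sequence that their reads are uncertain.

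**Figure D2:**
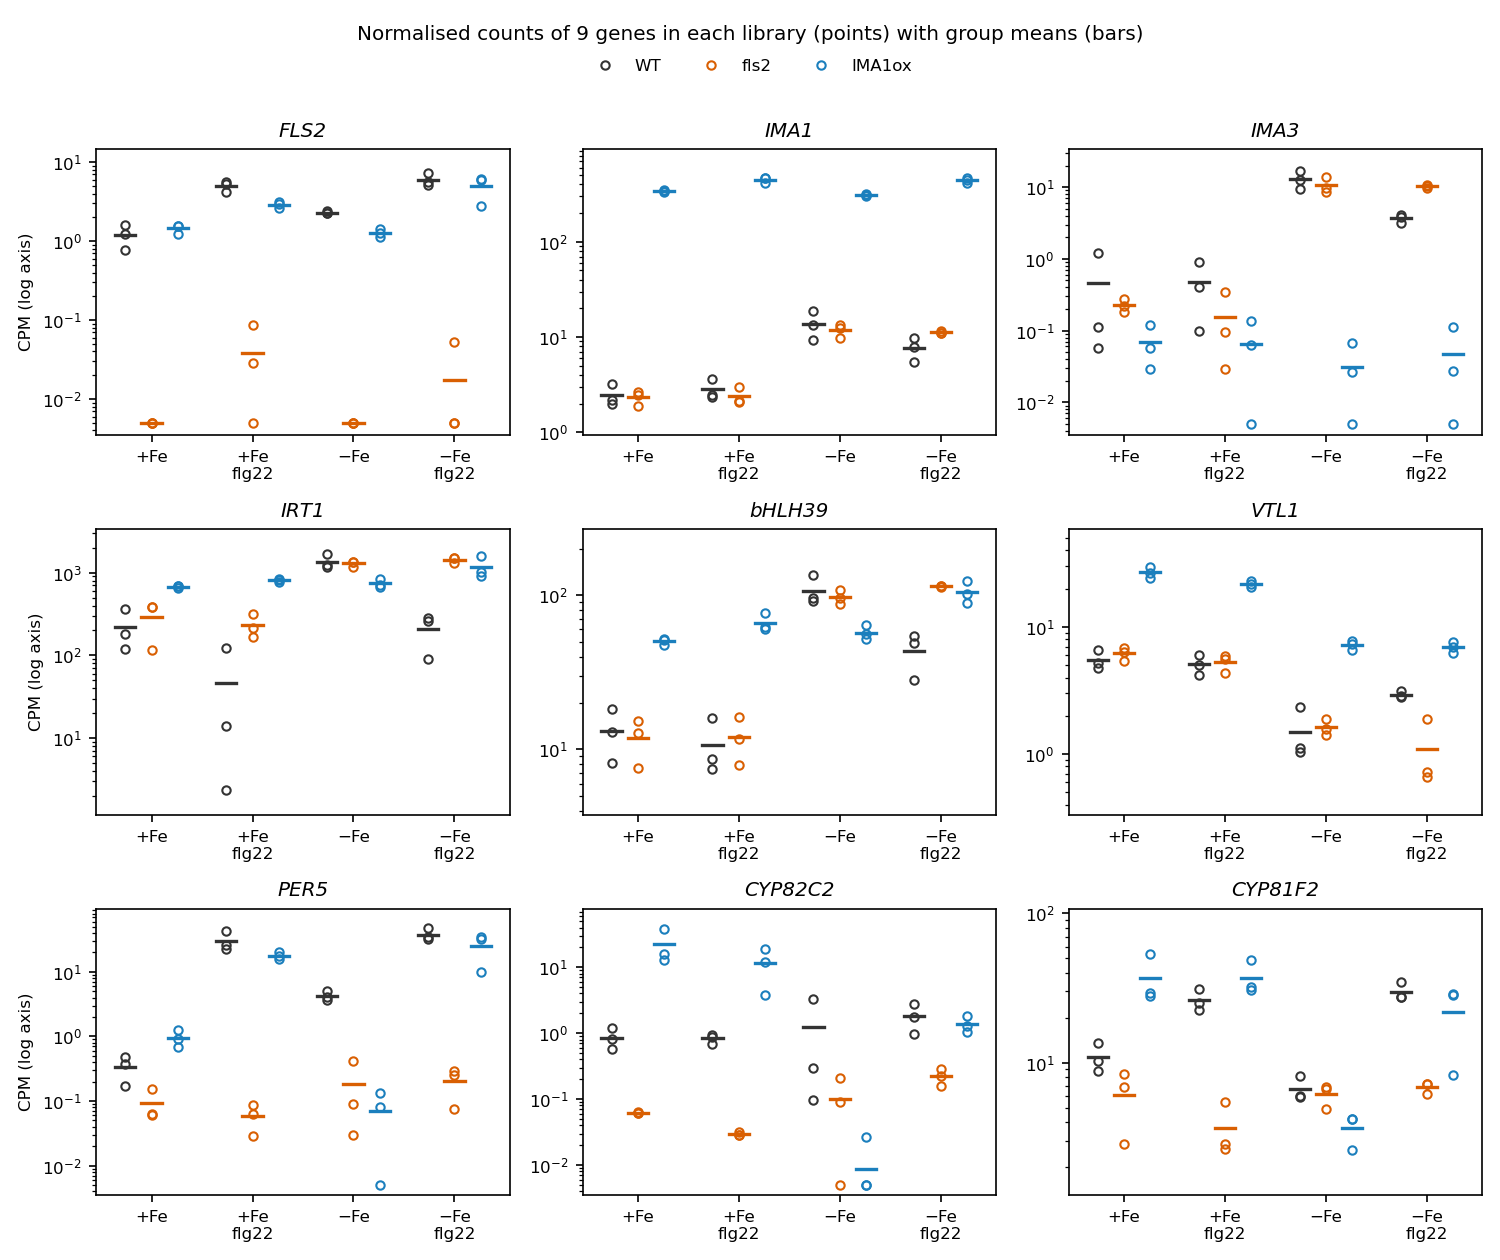
CPM of 9 genes (log axis) in each library, with points for libraries and bars for group means, by treatment and genotype. Libraries with no count are drawn at the lower edge of their panel. FLS2 was near the lower edge in fls2, and IMA1 was highest in IMA1ox under all 4 treatments.

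The comparison of Fe-deficient with Fe-sufficient WT asked which genes responded to Fe deficiency, and 1216 genes changed, 635 higher and 581 lower, against 580 and 634 by library totals alone. The largest rise was in IMA3 (AT2G30766), a relative of IMA1, with a log2 fold change of 4.94 ± 0.50 (adjusted p = 1.52e-07). AT3G02480 rose by 4.40 ± 0.55, bHLH100 (AT2G41240), a transcription factor of Fe uptake, by 4.05 ± 0.65, AT2G14247 by 3.96 ± 0.45, AT1G52120 by 3.88 ± 0.82 and AT2G30670 by 3.88 ± 0.85. Among genes that met the naming rule, the largest falls were in VTL1 (AT1G21140), a vacuolar iron transporter-like gene (-1.89 ± 0.25), the cytochrome P450 gene CYP81D11 (AT3G28740) (-1.45 ± 0.34), the amino acid transporter gene UMAMIT29 (AT4G01430) (-1.44 ± 0.19), CYP78A8 (AT1G01190) (-1.39 ± 0.21), the stress gene KIN1 (AT5G15960) (-1.35 ± 0.28) and FER1 (AT5G01600), a ferritin that stores Fe (-1.29 ± 0.24). Among the Fe deficiency regulators and their targets, 16 of 16 rose (16 adjusted over the list alone), with a median of 2.64 (camera adjusted p = 3.94e-52). bHLH38 (AT3G56970) rose by 3.38 ± 0.48, bHLH39 (AT3G56980) by 3.04 ± 0.30, the nicotianamine synthase gene NAS4 (AT1G56430) by 3.31 ± 0.35, the ubiquitin ligase gene BTS (AT3G18290) by 1.49 ± 0.10 and the regulator gene PYE (AT3G47640) by 1.18 ± 0.09. Among the genes of Fe uptake and coumarin synthesis that depend on the transcription factor FIT (AT2G28160), 13 of 17 rose (14 adjusted over the list alone), with a median of 1.14 (camera adjusted p = 4.69e-19). The Fe transporter gene IRT1 (AT4G19690) went from 220.4 ± 126 to 1360.1 ± 287 CPM (adjusted p = 0.0246), and the ferric chelate reductase gene FRO2 (AT1G01580) from 115 ± 87.3 to 941 ± 182 CPM (adjusted p = 0.0156). MYB72 (AT1G56160) rose by 3.23 ± 0.63 and CYP82C4 (AT4G31940), an enzyme of coumarin synthesis, had 2.23 ± 0.87 (adjusted p = 0.146), and 4.01 (adjusted p = 0.0239) without WT +Fe 2. Among the Fe storage genes, 7 of 7 fell (7 adjusted over the list alone), with a median of -1.13 (camera adjusted p = 1.40e-12), and VTL5 (AT3G25190) fell (-1.20 ± 0.27). Among the general phenylpropanoid genes, 6 of 6 rose (6 adjusted over the list alone) (camera adjusted p = 5.40e-09), with 4CL2 (AT3G21240) at 0.84 ± 0.11 and PAL2 (AT3G53260) at 0.62 ± 0.12. With 1 library left out, AT2G30670 (WT -Fe 2, adjusted p = 0.0675) lost the call. CYP81D11 (WT +Fe 2, WT -Fe 2, adjusted p from 0.0510 to 0.0554) did too. IRT1 (WT +Fe 1 or 3, WT -Fe 1, adjusted p from 0.0580 to 0.128) did too. FRO2 (WT +Fe 1 or 3, adjusted p from 0.0635 to 0.0992) did too. VTL5 (WT -Fe 2, adjusted p = 0.0613) did too. The count was 714 and 711 without WT +Fe 2 or 3. Fitting these 6 libraries alone left 373 genes and ended the calls of 20 of the 37 genes past the test whose values were followed here, IRT1, FRO2 and bHLH100 among them. IMA3 had 7.19, bHLH100 4.65, AT1G52120 5.35, FRO2 3.83 (from 3.03) and MYB72 4.52 without WT +Fe 2, AT3G02480 3.64, FER1 -1.91 and VTL5 -1.94 without WT -Fe 3, AT2G14247 5.33 without WT +Fe 1, AT1G52120 3.29 without WT +Fe 3, and AT1G52120 3.14 and AT2G30670 2.80 without WT -Fe 2.

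Other lists were also tested in Fe-deficient WT. Among the immunity markers, 5 of 18 rose and 1 fell (7 and 1 adjusted over the list alone) (camera adjusted p = 0.000113, adjusted p = 0.132 with an estimated correlation), and the peroxidase genes PER5 (AT1G14550) and PER4 (AT1G14540) rose by 3.60 ± 0.56 and 1.28 ± 0.31. Among the salicylic acid genes, 2 of 9 rose (3 adjusted over the list alone) (camera adjusted p = 0.00634, adjusted p = 0.253 with an estimated correlation), with the regulator gene SARD1 (AT1G73805) at 1.37 ± 0.30. Among the jasmonate genes, 1 of 9 rose (3 adjusted over the list alone), with a median of 0.24 and a mean of -0.18 (camera adjusted p = 0.0457, adjusted p = 0.390 with an estimated correlation). Among the suberin genes, 4 of 12 fell (7 adjusted over the list alone) (camera adjusted p = 3.17e-06, adjusted p = 0.132 with an estimated correlation), with MYB41 (AT4G28110) at -1.09 ± 0.20 and the acyltransferase gene GPAT5 (AT3G11430) at -0.51 ± 0.15. Among the zinc deficiency genes, 2 of 6 fell (3 adjusted over the list alone) (camera adjusted p = 0.000772), with the transporter gene ZIP5 (AT1G05300) at -0.77 ± 0.18. Among the copper-dependent genes, 2 of 3 rose (2 adjusted over the list alone) (camera adjusted p = 0.00478, adjusted p = 0.132 with an estimated correlation), with the superoxide dismutase gene CSD1 (AT1G08830) at 0.35 ± 0.08. Among the copper deficiency genes, 1 of 6 fell (1 rose and 4 fell adjusted over the list alone) (camera adjusted p = 0.0823). Among the Casparian strip and endodermis genes, none of 9 passed the test (1 rose adjusted over the list alone) (camera adjusted p = 0.0157, adjusted p = 0.427 with an estimated correlation). With 1 library left out, PER4 (WT +Fe 2, WT -Fe 3, adjusted p from 0.0542 to 0.0568) lost the call. GPAT5 (WT +Fe 1 or 2, WT -Fe 2 or 3, adjusted p from 0.0658 to 0.207) did too. ZIP5 (WT +Fe 3, WT -Fe 1, adjusted p from 0.0506 to 0.0984) did too. The call of GPAT5 was also lost with replicate number as a block, without the 2 libraries that stood apart and in a fit of these 6 libraries alone, which ended those of SARD1, ZIP5 and CSD1 too.

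The comparison of flg22-treated with untreated Fe-sufficient WT asked how roots responded to flg22, and 8170 genes changed, 4227 higher and 3943 lower, against 3811 and 4220 by library totals alone. CYP71B22 (AT3G26200), a cytochrome P450 gene, had no count in the untreated libraries and was at least 276-fold higher after flg22. AT4G28420 was 427-fold (95% counting interval 146 to 2074) higher. AT2G41810 rose by 7.94 ± 0.47, AT2G43620 by 7.26 ± 0.73, the glutathione transferase gene GSTU12 (AT1G69920) by 6.44 ± 0.92 and PER5 by 6.43 ± 0.48. The largest falls were in the arabinogalactan protein gene AGP30 (AT2G33790) (-5.35 ± 0.67), AT5G46900 (-5.07 ± 0.67), AT3G19430 (-4.29 ± 0.77), AT5G46890 (-4.16 ± 0.61), AT3G06460 (-4.13 ± 0.65) and the nitrate reductase gene NIA1 (AT1G77760) (-3.60 ± 0.40). Of the immunity markers, 15 of 18 rose (15 adjusted over the list alone), with a median of 1.07 (camera adjusted p = 8.10e-09). The receptor-like kinase gene FRK1 (AT2G19190) rose by 6.26 ± 0.68, and the transcription factor gene WRKY33 (AT2G38470) by 1.03 ± 0.15. Among the immune receptor genes, 4 of 4 rose (4 adjusted over the list alone) (camera adjusted p = 0.000247), with FLS2 at 2.04 ± 0.27 and the kinase gene BIK1 (AT2G39660) at 0.67 ± 0.07. Among the indole glucosinolate and camalexin genes, 4 of 6 rose (4 rose and 1 fell adjusted over the list alone) (camera adjusted p = 0.110), with the regulator gene MYB51 (AT1G18570) at 1.97 ± 0.23 and CYP81F2 (AT5G57220) at 1.26 ± 0.37. Among the ethylene genes, 6 of 9 rose (6 rose and 1 fell adjusted over the list alone) (camera adjusted p = 0.0483, adjusted p = 0.504 with an estimated correlation), with the synthesis gene ACS2 (AT1G01480) at 1.38 ± 0.31 and ERF6 (AT4G17490) at 1.26 ± 0.19. Of the jasmonate genes, 4 of 9 rose (4 adjusted over the list alone) (camera adjusted p = 0.0797), and the lipoxygenase gene LOX3 (AT1G17420) was 10.2-fold (95% counting interval 3.15 to 52.7) higher. LOX3 (WT +Fe flg22 2, adjusted p = 0.0874) lost the call with 1 library left out. GSTU12 had 8.59 without WT +Fe 1, GSTU12 5.82 without WT +Fe 3, and AGP30 -6.09 and AT3G19430 -5.00 without WT +Fe flg22 1.

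Among the FIT-dependent genes in the same comparison, 9 of 17 fell and 2 rose (9 and 2 adjusted over the list alone), with a median of -1.33 (camera adjusted p = 0.0195, adjusted p = 0.644 with an estimated correlation). IRT1 fell from 220.4 ± 126 to 45.9 ± 65.7 CPM (adjusted p = 0.0131) and FRO2 from 115 ± 87.3 to 27.8 ± 40.5 CPM (adjusted p = 0.0348). Of the Casparian strip and endodermis genes, 7 of 9 fell (7 adjusted over the list alone) (camera adjusted p = 0.000212, adjusted p = 0.504 with an estimated correlation), with the membrane domain gene CASP5 (AT5G15290) at -1.26 ± 0.30. Among the dividing cell genes, 5 of 7 fell (5 adjusted over the list alone) (camera adjusted p = 0.0270, adjusted p = 0.504 with an estimated correlation). Among the hypoxia genes, 6 of 8 fell (6 adjusted over the list alone) (camera adjusted p = 0.0459, adjusted p = 0.644 with an estimated correlation). Among the root hair genes, 4 of 7 fell and 1 rose (4 and 1 adjusted over the list alone) (camera adjusted p = 0.146), with the proline-rich protein gene PRP3 (AT3G62680) at -1.14 ± 0.27. Of the Fe deficiency regulators, 2 of 16 fell and 1 rose (1 and 1 adjusted over the list alone) (camera adjusted p = 0.793), with the transporter gene ZIF1 (AT5G13740) at 0.67 ± 0.11. Among the stele genes, 1 of 6 rose and 1 fell (1 and 1 adjusted over the list alone) (camera adjusted p = 0.743). Among the root cap genes, 1 of 3 rose (1 adjusted over the list alone) (camera adjusted p = 0.743). Among the phosphate starvation genes, 3 of 9 fell and 1 rose (3 and 1 adjusted over the list alone) (camera adjusted p = 0.680). Among the upstream bHLH regulators, 2 of 5 rose (2 adjusted over the list alone) (camera adjusted p = 0.473). Among the reference genes, 1 of 6 rose and 1 fell (1 and 1 adjusted over the list alone) (camera adjusted p = 0.895), with UBQ10 (AT4G05320), the polyubiquitin gene, at 0.27 ± 0.06. Green shoot genes summed to 390 ± 70.1 CPM after flg22 against 264 ± 38.1 CPM before, and 4 of 11 rose (4 adjusted over the list alone) (camera adjusted p = 0.146). Reads of the RBCS and LHCB1 copies on that list are uncertain because the copies are near identical. IRT1 (WT +Fe 2, WT +Fe flg22 1, adjusted p from 0.0722 to 0.0782) lost the call with 1 library left out. FRO2 (WT +Fe 2, WT +Fe flg22 1 or 2, adjusted p from 0.135 to 0.232) did too. In a fit of these 6 libraries alone, 8 of the 38 genes past the test whose values were followed here, IRT1 and FRO2 among them, lost their call. IRT1 had -4.76 (from -2.27) and FRO2 -4.68 (from -2.05) without WT +Fe flg22 3, and FRO2 -1.25 (from -2.05) without WT +Fe 2.

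Under Fe deficiency, flg22 changed 7118 genes in WT, 3707 higher and 3411 lower, against 3341 and 3722 by library totals alone. AT4G28420 was 698-fold (95% counting interval 193 to 5770.4) higher, CYP71B22 rose by 7.68 ± 1.01, AT2G43620 by 6.22 ± 0.65, AT2G41810 by 6.18 ± 0.43, FRK1 by 6.09 ± 0.66 and AT5G38930 by 5.75 ± 0.43. AGP30 fell (-6.55 ± 0.76), as did AT5G46900 (-4.63 ± 0.63), AT3G06460 (-4.52 ± 0.68), AT3G19430 (-4.38 ± 0.76), AT5G62330 (-4.25 ± 0.72) and the coumarin synthesis gene S8H (AT3G12900) (-3.99 ± 1.32). Of the FIT-dependent genes, 14 of 17 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -2.15 (camera adjusted p = 7.41e-07, adjusted p = 0.230 with an estimated correlation). IRT1 fell from 1360.1 ± 287 to 211 ± 106 CPM (adjusted p = 0.00459), FRO2 from 941 ± 182 to 125 ± 75.9 CPM (adjusted p = 0.00439) and FIT from 81.8 ± 12.3 to 27.96 ± 2.74 CPM (adjusted p = 3.50e-07). The transcription factor genes MYB72 and MYB10 (AT3G12820) had log2 fold changes of -2.40 ± 0.59 and -2.41 ± 0.39, and F6'H1 (AT3G13610), also of coumarin synthesis, of -0.74 ± 0.18. Among the Fe deficiency regulators, 16 of 16 fell (16 adjusted over the list alone), with a median of -1.09 (camera adjusted p = 1.01e-09, adjusted p = 0.121 with an estimated correlation). IMA1, IMA2 and IMA3 had log2 fold changes of -0.84 ± 0.20, -1.14 ± 0.24 and -1.80 ± 0.38, bHLH39 of -1.29 ± 0.27 and BTS of -0.74 ± 0.09. Of the Fe storage genes, 2 of 7 rose (3 adjusted over the list alone) (camera adjusted p = 0.168), with VTL1 at 0.98 ± 0.27. S8H (WT -Fe flg22 2 or 3, adjusted p from 0.0661 to 0.0792) lost the call with 1 library left out. VTL1 (WT -Fe 1, adjusted p = 0.0536) did too. The call of IMA3 was lost with DESeq2, and fits of these 6 libraries alone ended the calls of 5 of the 42 genes past the test whose values were followed here, IMA1, bHLH100 and MYB72 among them. CYP71B22 had 8.85 without WT -Fe 1, AT5G62330 -3.59 without WT -Fe 2, AT5G62330 -5.72 without WT -Fe flg22 2, and S8H -4.94 without WT -Fe flg22 1.

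Among the immunity markers in flg22-treated Fe-deficient WT, 14 of 18 rose and 1 fell (15 and 1 adjusted over the list alone) (camera adjusted p = 8.24e-07, adjusted p = 0.121 with an estimated correlation), with PER5 at 3.14 ± 0.34. Of the immune receptor genes, 4 of 4 rose (4 adjusted over the list alone) (camera adjusted p = 0.000887, adjusted p = 0.101 with an estimated correlation), with FLS2 at 1.39 ± 0.25. Of the indole glucosinolate and camalexin genes, 4 of 6 rose (4 adjusted over the list alone) (camera adjusted p = 0.00383, adjusted p = 0.121 with an estimated correlation), with CYP81F2 at 2.16 ± 0.38. Among the Casparian strip genes, 7 of 9 fell (7 adjusted over the list alone) (camera adjusted p = 3.84e-05, adjusted p = 0.210 with an estimated correlation), with CASP5 at -1.85 ± 0.28. Of the zinc deficiency genes, 3 of 6 rose (3 adjusted over the list alone) (camera adjusted p = 0.0481, adjusted p = 0.176 with an estimated correlation), with ZIP5 at 1.38 ± 0.17. Green shoot genes summed to 409 ± 159 CPM after flg22 against 249 ± 60.05 CPM before.

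Genes that responded to Fe deficiency were also chosen in fls2, whose libraries take no part in the WT comparisons, as those past the test with at least a 2-fold change. They were 62 raised and 22 lowered genes. In WT under Fe deficiency, 58 of the 62 raised genes rose. With flg22 in Fe-deficient WT, 54 of the raised genes fell and 3 rose, with a median of -1.37 (camera p = 1.34e-22, p = 0.0173 with an estimated correlation). With flg22 in Fe-sufficient WT, 18 of the raised genes fell and 7 rose, with a median of -0.23. The camera test of this list did not pass 0.05. Among the 22 lowered genes, 7 rose with flg22 in Fe-deficient WT. They were chosen on fls2 libraries, so their direction in fls2 is not independent evidence. With the compared groups alone, which chose their own genes, 30 raised ones fell with flg22 in Fe-deficient WT.

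**Figure D3:**
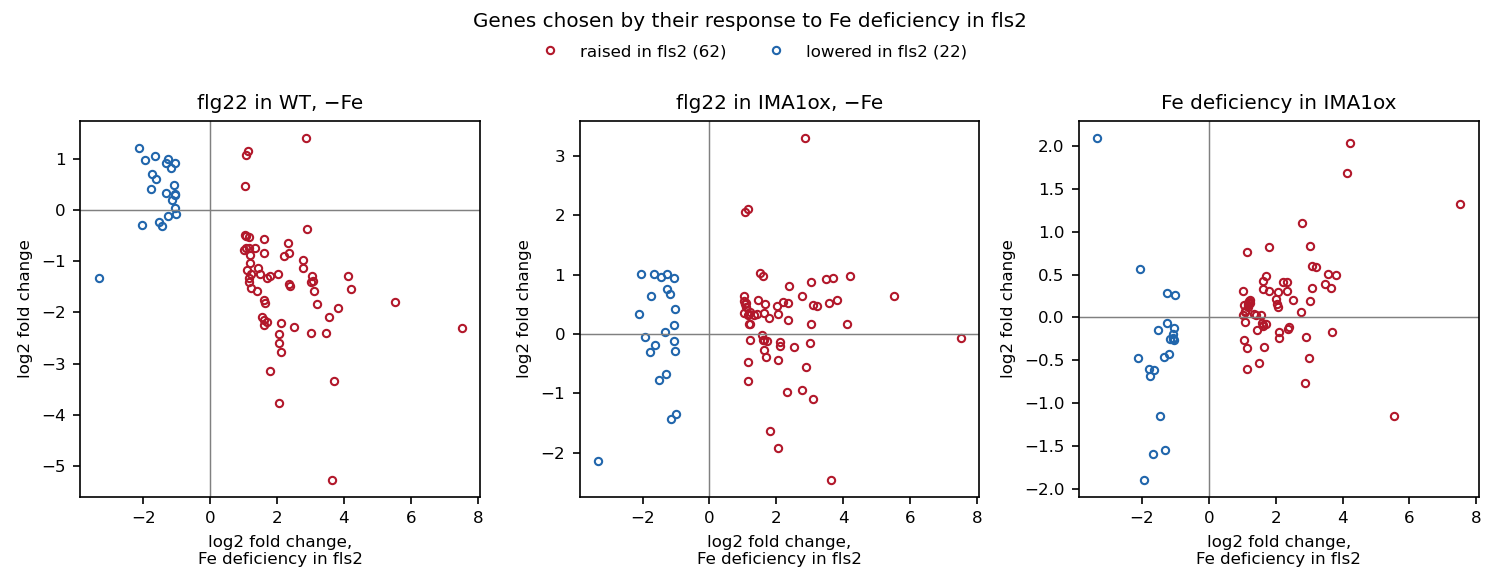
Log2 fold changes of the 62 raised and 22 lowered Fe-responsive genes, with 1 point per gene. The horizontal axis is the change with Fe deficiency in fls2 and the vertical axes are the changes named in the panels. In Fe-deficient WT, 54 of the raised genes fell with flg22.

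The test of the difference between the flg22 responses of Fe-deficient and Fe-sufficient WT found 50 genes, 23 with a higher and 27 with a lower response under Fe deficiency. The metal transporter genes ZIF1, HMA3 (AT4G30120) and IREG2 (AT5G03570) had differences of -1.24 ± 0.15, -1.61 ± 0.36 and -1.0 ± 0.19, BTS of -0.88 ± 0.13 and PER5 of -3.29 ± 0.65. The acyltransferase gene GPAT7 (AT5G06090), UMAMIT29 and scpl5 (AT1G73290) had 1.33 ± 0.27, 1.3 ± 0.27 and 1.25 ± 0.22. IRT1 had -0.42 ± 0.95 (adjusted p = 0.971), a value whose sign was opposite with limma-trend (0.62) and without WT +Fe flg22 3 (2.08). FRO2 had -0.86 ± 1.03 (adjusted p = 0.927), with the sign opposite without the same library (1.77). Of the Fe deficiency regulators, 4 of 16 were lower (13 adjusted over the list alone), with a median of -0.94 (camera adjusted p = 5.72e-22). Among the 62 raised genes, 10 were lower. Among the Fe storage genes, none of 7 passed the test (4 higher adjusted over the list alone) (camera adjusted p = 4.99e-08, adjusted p = 0.0575 with an estimated correlation). HMA3 (WT +Fe 1 or 3, WT +Fe flg22 1, 2 or 3, WT -Fe 1 or 3, WT -Fe flg22 1, 2 or 3, adjusted p from 0.0501 to 0.167) lost the call with 1 library left out. IREG2 (WT +Fe 1 or 3, WT -Fe flg22 2, adjusted p from 0.0513 to 0.0770) did too. PER5 (WT +Fe 1, 2 or 3, WT -Fe 3, WT -Fe flg22 2, adjusted p from 0.0516 to 0.0813) did too. GPAT7 (WT +Fe flg22 1, WT -Fe 3, WT -Fe flg22 2, adjusted p from 0.0516 to 0.0819) did too. UMAMIT29 (WT +Fe 1 or 2, WT +Fe flg22 2 or 3, WT -Fe 2 or 3, WT -Fe flg22 2 or 3, adjusted p from 0.0513 to 0.144) did too. The count was 30 without WT +Fe 3, 33 without WT +Fe flg22 1 and 21 without WT -Fe flg22 2, 129 with DESeq2 and 89 without the 2 libraries that stood apart. A fit of these 12 libraries alone left 19 genes and ended the calls of GPAT7, UMAMIT29, PER5, HMA3 and BTS. The call of PER5 was also lost with limma-trend, that of HMA3 with no filter on low counts or with replicate number as a block, and that of UMAMIT29 without the 2 libraries that stood apart.

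In fls2, Fe deficiency changed 431 genes, 234 higher and 197 lower, and by library totals alone the split was 206 and 283. IMA3 rose by 5.52 ± 0.55, AT2G14247 by 3.81 ± 0.46 and bHLH100 by 3.56 ± 0.64. VTL1 fell (-1.94 ± 0.24), as did UMAMIT29 (-1.75 ± 0.20) and the zinc and copper transporter gene ZIP2 (AT5G59520) (-1.78 ± 0.45). Among the Fe deficiency regulators, 16 of 16 rose (16 adjusted over the list alone) (camera adjusted p = 5.21e-64). Among the FIT-dependent genes, 11 of 17 rose (16 adjusted over the list alone) (camera adjusted p = 8.17e-23). IRT1 had 2.14 ± 0.69 (adjusted p = 0.122) and FRO2 2.46 ± 0.74 (adjusted p = 0.0938), and MYB72 rose by 3.03 ± 0.62. Of the Fe storage genes, 6 of 7 fell (7 adjusted over the list alone) (camera adjusted p = 1.94e-16). Of the copper deficiency genes, 3 of 6 fell (5 adjusted over the list alone) (camera adjusted p = 7.20e-06, adjusted p = 0.0925 with an estimated correlation). Among the genes called in WT and in fls2, 196 were higher in both, where 7.30 are expected by chance, and 146 were lower in both, where 5.62 are expected. The test of the difference between WT and fls2 in Fe deficiency found 0 genes with edgeR, 0 with DESeq2 and 0 with limma-trend, with 607 genes at an unadjusted p under 0.05. ZIP2 (fls2 +Fe 1, 2 or 3, fls2 -Fe 1 or 3, adjusted p from 0.0658 to 0.197) lost the call with 1 library left out. MYB72 (fls2 +Fe 1, adjusted p = 0.0532) did too. The count was 255 without fls2 +Fe 2, and 286 and 278 without fls2 -Fe 1 or 2. Fitting these 6 libraries alone ended the calls of bHLH100, bHLH38 and ZIP2.

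With flg22 in fls2, edgeR, DESeq2 and limma-trend each found 0 changed genes under Fe deficiency and 0 with Fe, with 807 and 648 genes at an unadjusted p under 0.05, and a fit of the 6 Fe-deficient libraries alone gave 9 genes, all lower. The tests of the difference between fls2 and WT in the flg22 response found 4318 genes under Fe deficiency and 4113 with Fe. Under Fe deficiency, AGP30, AT3G06460 and AT3G19430 differed by 6.90 ± 0.91, 4.97 ± 0.84 and 4.72 ± 0.97, and AT5G38930, AT2G43620 and AT2G41810 by -7.66 ± 1.12, -6.72 ± 1.47 and -6.64 ± 1.13. IRT1 stood at 1439 ± 109 CPM in flg22-treated and 1293 ± 105 CPM in untreated Fe-deficient fls2, a difference from WT of 2.84 ± 0.95 (adjusted p = 0.0351), and FRO2 differed by 3.12 ± 1.02 (adjusted p = 0.0309). FIT differed by 1.85 ± 0.24, bHLH39 by 1.53 ± 0.38, IMA3 by 1.76 ± 0.51 and FRK1 by -6.51 ± 1.6. Of the FIT-dependent genes, 14 of 17 were higher and 1 lower (14 and 1 adjusted over the list alone) (camera adjusted p = 2.21e-07, adjusted p = 0.198 with an estimated correlation). Of the immunity markers, 13 of 18 were lower and 1 higher (15 and 1 adjusted over the list alone) (camera adjusted p = 8.39e-07, adjusted p = 0.108 with an estimated correlation). With Fe, AGP30, AT5G46900 and AT3G06460 differed by 5.52 ± 0.83, 5.02 ± 0.83 and 4.22 ± 0.81, GSTU12, AT2G43620 and AT2G41810 by -8.85 ± 2.07, -7.54 ± 1.83 and -7.45 ± 1.52, and FRK1 by -5.62 ± 1.90. Green shoot genes summed to 157 ± 11.3 CPM in flg22-treated and 156 ± 16.9 CPM in untreated Fe-deficient fls2, and to 213 ± 18.95 and 199.99 ± 30.7 CPM with Fe. IRT1 (WT -Fe 1 or 2, WT -Fe flg22 2 or 3, fls2 -Fe 1, 2 or 3, fls2 -Fe flg22 2 or 3, adjusted p from 0.0501 to 0.0853) lost the call with 1 library left out. FRO2 (WT -Fe 1, WT -Fe flg22 2, fls2 -Fe 1, 2 or 3, fls2 -Fe flg22 2, adjusted p from 0.0535 to 0.0748) did too. GSTU12 (fls2 +Fe 3, adjusted p = 0.0520) did too. AT2G41810 (fls2 +Fe 1, adjusted p = 0.299) did too. FRK1 (WT +Fe 1 or 2, WT +Fe flg22 1 or 2, fls2 +Fe 1 or 2, fls2 +Fe flg22 2 or 3, adjusted p from 0.0505 to 0.330) did too. The call of IMA3 was also lost with DESeq2. The count with Fe was 2712 and 2552 without WT +Fe flg22 1 or 2. AT5G38930 had -8.24 and AT2G41810 -7.51 without fls2 -Fe flg22 2, AGP30 6.27 without WT +Fe flg22 1, GSTU12 -11.00 without WT +Fe 1, GSTU12 -8.23 without WT +Fe 3, GSTU12 -8.04 without fls2 +Fe 3, GSTU12 -9.94 and AT2G41810 -8.37 without fls2 +Fe flg22 2, GSTU12 -8.26 without fls2 +Fe flg22 3, and AT2G41810 -5.26 and FRK1 -4.45 without fls2 +Fe 1.

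Between untreated fls2 and WT with Fe, 4 genes differed, all lower in fls2. They were FLS2, the growth repressor gene RGL2 (AT3G03450) (-2.55 ± 0.17), AT5G26270 (-0.88 ± 0.15) and the xanthine dehydrogenase gene XDH2 (AT4G34900) (-4.31 ± 0.69), the last named after its values were seen. Among the immune receptor genes, 1 of 4 was lower (2 adjusted over the list alone) (camera adjusted p = 3.77e-06). The lower one is FLS2, the mutated gene, and without it the list did not pass (adjusted p = 0.166) and 2 of the lists passed, against 7 with it. Green shoot genes had a median of -0.25 and a mean of 0.42 (camera adjusted p = 0.0484, adjusted p = 0.969 with an estimated correlation). AT5G26270 (WT +Fe 3, fls2 +Fe 2 or 3, adjusted p from 0.0643 to 0.189) lost the call with 1 library left out. XDH2 (fls2 +Fe 2, adjusted p = 0.0961) did too. Without fls2 +Fe 2 the count was 2, and DESeq2 gave 11 genes, 2 higher and 9 lower. A fit of these 6 libraries alone left 2 genes and ended the calls of FLS2, AT5G26270 and XDH2.

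The comparison of IMA1ox with WT with Fe asked what IMA1 expression changed without Fe deficiency, and 3404 genes differed, 1443 higher and 1961 lower, against 2920 higher and 1475 lower by library totals alone. AT1G75945 had no count in WT and was at least 169-fold higher in IMA1ox. After IMA1 (7.14 ± 0.23), the largest differences were in the defence lipase gene GLIP1 (AT5G40990) (6.39 ± 0.73), the glutathione transferase gene GSTF3 (AT2G02930) (4.73 ± 0.64), the cytochrome P450 gene CYP82C2 (AT4G31970) (4.68 ± 0.66) and AT1G26240 (4.0 ± 0.47). Lower in IMA1ox were the metal reductase gene FRO4 (AT5G23980) (-6.22 ± 1.38), AT5G33355 (-4.65 ± 0.38), CYP710A4 (AT2G28860) (-3.51 ± 0.51), AT3G59930 (-3.08 ± 0.30), AT3G02620 (-2.94 ± 0.29) and ZIP2 (-2.46 ± 0.49). Of the Fe deficiency regulators, 12 of 16 were higher and 2 lower (12 and 3 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 6.87e-08, adjusted p = 0.157 with an estimated correlation). The overexpressed IMA1 is on this list, and without it 11 of 15 were higher and 2 lower, with a median of 0.57 (adjusted p = 1.02e-05, adjusted p = 0.217 with an estimated correlation). bHLH100, bHLH101 (AT5G04150), bHLH38 and bHLH39 were higher by 2.57 ± 0.64, 2.09 ± 0.26, 1.66 ± 0.47 and 1.95 ± 0.30, and IMA2 was lower (-1.14 ± 0.32). Among the FIT-dependent genes, 5 of 17 were higher (6 adjusted over the list alone) (camera adjusted p = 0.00134, adjusted p = 0.319 with an estimated correlation), with the vacuolar zinc transporter gene MTP3 (AT3G58810) at 1.12 ± 0.26. IRT1 had 1.63 ± 0.68 (adjusted p = 0.102) and FRO2 1.44 ± 0.72 (adjusted p = 0.179). Among the Fe storage genes, 6 of 7 were higher (7 adjusted over the list alone) (camera adjusted p = 3.32e-07, adjusted p = 0.0863 with an estimated correlation), with VTL1 at 2.29 ± 0.20 and FER1 at 1.29 ± 0.23. Among the 62 genes raised by Fe deficiency in fls2, 29 were higher and 2 lower in IMA1ox, with a median of 0.72 (camera p = 1.83e-15, p = 0.0485 with an estimated correlation). IMA1 is one of them, and without it 28 of 61 were higher, with a median of 0.71 (p = 5.40e-14, p = 0.0596 with an estimated correlation). bHLH38 (WT +Fe 1 or 3, adjusted p from 0.0517 to 0.0984) lost the call with 1 library left out. IMA2 (WT +Fe 2, IMA1ox +Fe 1, adjusted p from 0.0603 to 0.0731) did too. The count was 2206 without IMA1ox +Fe 3 and 2143 without WT +Fe 3 (18 of the raised genes higher), and the raised genes that were lower numbered 0 without WT +Fe 2 or IMA1ox +Fe 1 and 1 without IMA1ox +Fe 2 or 3. A fit of these 6 libraries alone ended the calls of FRO4, ZIP2 and bHLH38. GLIP1 had 8.12 without WT +Fe 1, GLIP1 5.78, CYP82C2 4.04 and AT1G26240 3.20 without IMA1ox +Fe 3, GSTF3 5.80 without WT +Fe 3, FRO4 -5.50 and bHLH100 3.17 without WT +Fe 2, and FRO4 -6.82 and AT5G33355 -5.26 without IMA1ox +Fe 1.

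Immune and tissue lists also differed between IMA1ox and WT with Fe. Among the immunity markers, 7 of 18 were higher (8 adjusted over the list alone) (camera adjusted p = 1.40e-05, adjusted p = 0.157 with an estimated correlation), with WRKY53 (AT4G23810) at 1.12 ± 0.20. Among the indole glucosinolate and camalexin genes, 4 of 6 were higher and 1 lower (4 and 1 adjusted over the list alone) (camera adjusted p = 0.0140, adjusted p = 0.189 with an estimated correlation), with CYP81F2 at 1.76 ± 0.36 and the camalexin synthesis gene PAD3 (AT3G26830) at 1.44 ± 0.31. Among the copper deficiency genes, 4 of 6 were lower (5 adjusted over the list alone) (camera adjusted p = 0.00434, adjusted p = 0.319 with an estimated correlation). Among the zinc deficiency genes, 4 of 6 were lower (4 adjusted over the list alone) (camera adjusted p = 0.000740), with ZIP5 at -1.38 ± 0.18. Of the root hair genes, 4 of 7 were lower (1 higher and 4 lower adjusted over the list alone) (camera adjusted p = 0.0140, adjusted p = 0.319 with an estimated correlation), with PRP3 at -0.99 ± 0.27 and the cell wall gene LRX1 (AT1G12040) at -0.90 ± 0.18. Of the Casparian strip genes, 6 of 9 were lower (6 adjusted over the list alone) (camera adjusted p = 0.00134, adjusted p = 0.319 with an estimated correlation). Of the dividing cell genes, 2 of 7 were higher (3 adjusted over the list alone) (camera adjusted p = 0.0141, adjusted p = 0.319 with an estimated correlation). Among the green shoot genes, 5 of 11 were lower (6 adjusted over the list alone) (camera adjusted p = 0.00395, adjusted p = 0.319 with an estimated correlation), and their sum was 161 ± 26.2 CPM against 264 ± 38.1 CPM. PRP3 (WT +Fe 1, adjusted p = 0.0760) lost the call with 1 library left out. The call of PAD3 was lost in a fit of these 6 libraries alone.

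Under Fe deficiency, 2423 genes differed between IMA1ox and WT, 844 higher and 1579 lower, against 2296 higher and 1007 lower by library totals alone. IMA3 was 461-fold (95% counting interval 157 to 2237) lower in IMA1ox, and NAS4 and IMA2 differed by -3.97 ± 0.37 and -2.92 ± 0.26. IMA1, the thioredoxin gene TH8 (AT1G69880) and VTL1 were higher by 4.48 ± 0.19, 2.68 ± 0.58 and 2.29 ± 0.24, and ARD3 (AT2G26400) was lower (-4.27 ± 1.04). Among the Fe deficiency regulators, 13 of 16 were lower and 1 higher (14 and 1 adjusted over the list alone) (camera adjusted p = 9.48e-14). The member that was higher is IMA1, and without it the adjusted p was 2.27e-19 (0.0135 with an estimated correlation). Of the FIT-dependent genes, 11 of 17 were lower (11 adjusted over the list alone) (camera adjusted p = 5.73e-08, adjusted p = 0.256 with an estimated correlation), with MYB72 at -2.11 ± 0.57. Of the Fe storage genes, 7 of 7 were higher (7 adjusted over the list alone) (camera adjusted p = 3.73e-12). Among the phenylpropanoid genes, 6 of 6 were lower (6 adjusted over the list alone) (camera adjusted p = 1.24e-10). Of the salicylic acid genes, 5 of 9 were lower (6 adjusted over the list alone) (camera adjusted p = 0.000522, adjusted p = 0.218 with an estimated correlation), with the regulator gene CBP60G (AT5G26920) at -1.89 ± 0.35. PER5 and PER4 differed by -5.75 ± 0.73 and -3.53 ± 0.38. Of the 62 raised genes, 46 were lower and 1, IMA1, higher, with a median of -1.10 (camera p = 1.28e-28, p = 0.00781 with an estimated correlation). Green shoot genes summed to 158 ± 11.5 CPM in IMA1ox and 249 ± 60.05 CPM in WT. ARD3 (WT -Fe 2, adjusted p = 0.277) lost the call with 1 library left out. MYB72 (WT -Fe 1, IMA1ox -Fe 2 or 3, adjusted p from 0.0584 to 0.0778) did too. The count was 1607 and 1565 without IMA1ox -Fe 1 or 3, and 1004 in a fit of these 6 libraries alone, which ended the call of ARD3. The call of MYB72 was also lost with DESeq2 (adjusted p = 0.0668). ARD3 had -1.65 without WT -Fe 2, and PER5 -6.47 without IMA1ox -Fe 1.

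In IMA1ox, Fe deficiency changed 873 genes, 387 higher and 486 lower. CYP82C2 was 2309-fold (95% counting interval 414 to 91227) lower and GLIP1 186-fold (95% counting interval 63.3 to 904) lower under Fe deficiency, and AT1G26380 fell (-6.48 ± 0.82). AT5G33355 rose by 3.34 ± 0.39, G3Pp2 (AT4G25220), a phosphate-linked transporter gene, by 2.14 ± 0.33 and AT5G26080 by 2.04 ± 0.33. Of the Fe deficiency regulators, 1 of 16 rose (1 adjusted over the list alone) (camera adjusted p = 0.134), with bHLH38 at 0.59 ± 0.43 (adjusted p = 0.582) and IMA2, the member that rose, at 1.11 ± 0.32. IRT1 had 0.13 ± 0.66 (adjusted p = 0.957) and FRO2 0.10 ± 0.70 (adjusted p = 0.971), with the sign of FRO2 opposite without IMA1ox -Fe 1 (-0.09). Of the 62 genes raised in fls2, 1 rose, with a median of 0.15 (camera p = 0.0240, p = 0.561 with an estimated correlation). Among the Fe storage genes, 3 of 7 fell (5 adjusted over the list alone) (camera adjusted p = 7.48e-08, adjusted p = 0.0627 with an estimated correlation), with VTL1 at -1.89 ± 0.20 and VTL5 at -1.59 ± 0.26. Of the indole glucosinolate and camalexin genes, 5 of 6 fell (6 adjusted over the list alone), with a median of -1.3 (camera adjusted p = 5.18e-12), and CYP81F2 and PAD3 had -3.35 ± 0.41 and -1.97 ± 0.32. Among the root hair genes, 4 of 7 rose (5 adjusted over the list alone) (camera adjusted p = 2.00e-05, adjusted p = 0.139 with an estimated correlation), with PRP3 at 0.99 ± 0.27 and LRX1 at 0.86 ± 0.18. Among the Casparian strip genes, 4 of 9 rose (7 adjusted over the list alone) (camera adjusted p = 3.70e-07, adjusted p = 0.139 with an estimated correlation). PER5 and PER4 fell (-3.59 ± 0.96 and -2.72 ± 0.40). IMA2 (IMA1ox +Fe 1, 2 or 3, IMA1ox -Fe 2 or 3, adjusted p from 0.0823 to 0.183) lost the call with 1 library left out. PRP3 (IMA1ox +Fe 1, 2 or 3, IMA1ox -Fe 1, 2 or 3, adjusted p from 0.0694 to 0.121) did too. PER5 (IMA1ox +Fe 1 or 3, IMA1ox -Fe 1, 2 or 3, adjusted p from 0.0668 to 0.105) did too. The count ran from 470 to 672 with 1 library left out, at 558 and 470 without IMA1ox +Fe 2 or 3 and at 560, 542 and 520 without IMA1ox -Fe 1, 2 or 3, and was 1379 in a fit of these 6 libraries alone. The call of IMA2 was also lost with replicate number as a block, that of PER5 with limma-trend and that of PAD3 in that fit. AT5G33355 had 3.95 without IMA1ox +Fe 1, and PER5 -4.31 without IMA1ox -Fe 1.

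The test of the difference between IMA1ox and WT in the response to Fe deficiency found 818 genes, 348 with a higher and 470 with a lower response in IMA1ox. AT5G33355, G3Pp2 and AT1G34047 differed by 4.2 ± 0.49, 3.4 ± 0.46 and 2.72 ± 0.54, and AT1G26380 by -6.11 ± 1.19. CYP82C2 and GLIP1 also had a lower response in IMA1ox (adjusted p = 0.000120 and adjusted p = 0.0381), and rested on at most 3 counts in Fe-deficient IMA1ox. bHLH100, bHLH101, bHLH39 and MYB10 differed by -3.54 ± 0.85, -2.88 ± 0.33, -2.86 ± 0.40 and -2.35 ± 0.54, and PER5, PER4 and CYP81F2 by -7.20 ± 1.08, -4.0 ± 0.51 and -2.64 ± 0.57. Among the Fe deficiency regulators, 15 of 16 were lower (16 adjusted over the list alone), with a median of -2.23 (camera adjusted p = 5.74e-39), and without IMA1 14 of 15, with a median of -1.81. Among the FIT-dependent genes, 8 of 17 were lower (15 adjusted over the list alone) (camera adjusted p = 7.84e-16, adjusted p = 0.0544 with an estimated correlation). Among the indole glucosinolate and camalexin genes, 3 of 6 were lower (4 adjusted over the list alone) (camera adjusted p = 3.02e-05). Among the 62 raised genes, 44 had a lower response, IMA1 among them. GLIP1 (WT +Fe 2 or 3, WT -Fe 1 or 3, IMA1ox -Fe 2 or 3, adjusted p from 0.0595 to 0.179) lost the call with 1 library left out. bHLH100 (WT +Fe 3, adjusted p = 0.0517) did too. The call of GLIP1 was also lost without the 2 libraries that stood apart and in a fit of these 12 libraries alone. Without IMA1ox +Fe 3 the count was 531. AT5G33355 had 4.81 without IMA1ox +Fe 1, AT1G26380 -5.25 without WT -Fe 3, bHLH100 -4.14 without WT +Fe 2, and PER5 -7.91 without IMA1ox -Fe 1.

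In Fe-deficient IMA1ox, flg22 changed 9262 genes, 4890 higher and 4372 lower, against 3984 and 5545 by library totals alone. AT1G67270 was 639-fold (95% counting interval 218 to 3099) higher and CYP71B22 751-fold (95% counting interval 134 to 29709.8) higher, and PER5 rose by 8.32 ± 0.60. AT3G22142, the arabinogalactan protein gene FLA6 (AT2G20520) and AT3G04330 fell (-6.72 ± 1.40, -3.31 ± 0.50 and -3.28 ± 0.36). Of the immunity markers, 15 of 18 rose (15 adjusted over the list alone) (camera adjusted p = 3.43e-08, adjusted p = 0.0625 with an estimated correlation), with FRK1 at 5.78 ± 0.66. Of the FIT-dependent genes, 5 of 17 rose (4 adjusted over the list alone) (camera adjusted p = 0.332), with the metal transporter gene NRAMP1 (AT1G80830) at 1.05 ± 0.08. IRT1 had 0.66 ± 0.66 (adjusted p = 0.436) and FRO2 0.34 ± 0.70 (adjusted p = 0.724), with the sign of FRO2 opposite without IMA1ox -Fe flg22 1 (-0.18). Of the Fe deficiency regulators, 8 of 16 rose and 1 fell (9 and 2 adjusted over the list alone) (camera adjusted p = 0.0811), with ZIF1 at 0.97 ± 0.10, bHLH39 at 0.88 ± 0.27 and IMA2 at -0.95 ± 0.31. Of the 62 raised genes, 20 rose, IMA1 among them, and 4 fell, with a median of 0.34. The camera test of this list did not pass 0.05. Without IMA1ox -Fe flg22 2 12 rose and 2 fell. Of the root hair genes, 7 of 7 fell (7 adjusted over the list alone) (camera adjusted p = 3.79e-05, adjusted p = 0.138 with an estimated correlation), with the root hair regulator gene RSL4 (AT1G27740) at -1.36 ± 0.25. Of the Casparian strip genes, 7 of 9 fell (7 adjusted over the list alone) (camera adjusted p = 0.00128, adjusted p = 0.419 with an estimated correlation), with CASP2 (AT3G11550) at -0.86 ± 0.12. Green shoot genes summed to 227 ± 38.7 CPM after flg22 against 158 ± 11.5 CPM before. bHLH39 (IMA1ox -Fe flg22 2, adjusted p = 0.0578) lost the call with 1 library left out. IMA2 (IMA1ox -Fe 3, IMA1ox -Fe flg22 2, adjusted p from 0.0671 to 0.126) did too. The call of IMA2 was lost in a fit of these 6 libraries alone. PER5 had 9.04 without IMA1ox -Fe 1, AT3G22142 -6.09 and FRK1 6.39 without IMA1ox -Fe 2, and FLA6 -4.69 without IMA1ox -Fe flg22 1.

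With Fe, flg22 changed 8842 genes in IMA1ox, 4690 higher and 4152 lower, against 3858 and 4914 by library totals alone. AT1G67270, CYP71B22 and AT2G43620 rose by 4.44 ± 0.56, 4.43 ± 0.67 and 4.43 ± 0.62, and AGP30, AT3G19430 and AT3G04330 fell (-5.58 ± 0.67, -5.12 ± 0.80 and -4.98 ± 0.45). Among the immunity markers, 15 of 18 rose (15 adjusted over the list alone) (camera adjusted p = 3.99e-06, adjusted p = 0.165 with an estimated correlation), with FRK1 at 3.59 ± 0.57 and PER5 at 4.2 ± 0.42. Among the FIT-dependent genes, 2 of 17 rose and 1 fell (1 rose adjusted over the list alone) (camera adjusted p = 0.999), with a median of -0.07 against an upward direction in the test, and IRT1 had 0.25 ± 0.66 (adjusted p = 0.782). Among the dividing cell genes, 7 of 7 fell (7 adjusted over the list alone) (camera adjusted p = 0.00364, adjusted p = 0.353 with an estimated correlation). Among the root hair genes, 5 of 7 fell (6 adjusted over the list alone) (camera adjusted p = 0.00994, adjusted p = 0.471 with an estimated correlation). Green shoot genes summed to 239 ± 34.5 CPM after flg22 against 161 ± 26.2 CPM before.

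The tests of the difference between IMA1ox and WT in the flg22 response found 585 genes under Fe deficiency, 422 with a higher and 163 with a lower response in IMA1ox (315 and 201 by library totals alone), and 176 genes with Fe. Under Fe deficiency, ARD3, PER5 and the sugar-starvation gene DIN11 (AT3G49620) differed by 5.29 ± 1.42, 5.18 ± 0.85 and 4.56 ± 0.78, and AT2G41810, KIN1 and the root hair regulator gene RSL2 (AT4G33880) by -4.96 ± 1.26, -1.63 ± 0.41 and -1.49 ± 0.28. MYB10, bHLH38 and bHLH39 differed by 2.76 ± 0.53, 2.29 ± 0.61 and 2.17 ± 0.38, and IRT1 had 3.35 ± 0.96 (adjusted p = 0.0576). Of the FIT-dependent genes, 8 of 17 were higher (13 adjusted over the list alone), with a median of 2.06 (camera adjusted p = 3.25e-19). Among the Fe deficiency regulators, 12 of 16 were higher (13 adjusted over the list alone) (camera adjusted p = 1.39e-23), and without IMA1 11 of 15. Among the 62 raised genes, 36 had a higher response in IMA1ox, IMA1 among them, with a median of 1.67 (camera p = 3.53e-51, p = 0.000611 with an estimated correlation). Of the root hair genes, 2 of 7 were lower (5 adjusted over the list alone) (camera adjusted p = 9.63e-07, adjusted p = 0.0928 with an estimated correlation), with the expansin gene EXPA7 (AT1G12560) at -0.97 ± 0.18. Among the salicylic acid genes, 3 of 9 were higher (5 adjusted over the list alone) (camera adjusted p = 0.000226, adjusted p = 0.137 with an estimated correlation), with the immune monooxygenase gene FMO1 (AT1G19250) at 2.75 ± 0.73. Of the suberin genes, 3 of 12 were lower (8 adjusted over the list alone) (camera adjusted p = 3.51e-08, adjusted p = 0.0997 with an estimated correlation), with GPAT5 at -0.81 ± 0.22. With Fe, AT3G27400, NIA1 and AT1G03820 differed by 3.03 ± 0.71, 2.66 ± 0.52 and 2.19 ± 0.54, and AT2G41810, the nitrate transporter gene NRT1.8 (AT4G21680) and the glutathione transferase gene GSTF6 (AT1G02930) by -7.22 ± 1.51, -3.51 ± 0.71 and -3.05 ± 0.67. ARD3 (WT -Fe 2, WT -Fe flg22 1, 2 or 3, IMA1ox -Fe 1, 2 or 3, IMA1ox -Fe flg22 2 or 3, adjusted p from 0.0602 to 0.269) lost the call with 1 library left out. AT2G41810 (IMA1ox -Fe 1, 2 or 3, adjusted p from 0.0643 to 0.138) did too. KIN1 (WT -Fe 1 or 3, WT -Fe flg22 2 or 3, IMA1ox -Fe 2, IMA1ox -Fe flg22 1 or 2, adjusted p from 0.0582 to 0.0949) did too. bHLH38 (WT -Fe 1, WT -Fe flg22 2, IMA1ox -Fe 1, 2 or 3, IMA1ox -Fe flg22 2, adjusted p from 0.0665 to 0.124) did too. FMO1 (WT -Fe 2, WT -Fe flg22 1, 2 or 3, IMA1ox -Fe 1, 2 or 3, IMA1ox -Fe flg22 2, adjusted p from 0.0579 to 0.137) did too. GPAT5 (WT -Fe 3, WT -Fe flg22 2 or 3, IMA1ox -Fe 1 or 3, IMA1ox -Fe flg22 1, 2 or 3, adjusted p from 0.0608 to 0.145) did too. AT3G27400 (WT +Fe 2, WT +Fe flg22 1 or 2, IMA1ox +Fe 1 or 3, IMA1ox +Fe flg22 1 or 2, adjusted p from 0.0724 to 0.144) did too. NIA1 (WT +Fe 2, WT +Fe flg22 1, adjusted p from 0.0547 to 0.0576) did too. AT1G03820 (WT +Fe 2 or 3, WT +Fe flg22 1 or 2, IMA1ox +Fe 1, 2 or 3, IMA1ox +Fe flg22 1 or 2, adjusted p from 0.0518 to 0.178) did too. AT2G41810 (IMA1ox +Fe 1 or 2, adjusted p from 0.0833 to 0.119) did too. NRT1.8 (WT +Fe 2, WT +Fe flg22 1, IMA1ox +Fe 3, adjusted p from 0.0520 to 0.0794) did too. GSTF6 (WT +Fe 1, 2 or 3, WT +Fe flg22 1, IMA1ox +Fe 3, IMA1ox +Fe flg22 1 or 3, adjusted p from 0.0530 to 0.0909) did too. The count under Fe deficiency was 319 without WT -Fe flg22 2, 377 without IMA1ox -Fe 3 and 163 in a fit of those 12 libraries alone, which ended the calls of 10 of the 12 genes past the test whose values were followed here, ARD3, PER5, DIN11, MYB10 and EXPA7 among them. The calls of ARD3 and FMO1 were also lost with limma-trend, those of ARD3 and GPAT5 with replicate number as a block, and those of KIN1 and GPAT5 without the 2 libraries that stood apart. With Fe it was 49 and 104 without WT +Fe 2 or 3, 63 and 116 without WT +Fe flg22 1 or 3, 90 and 64 without IMA1ox +Fe 1 or 3, 64 and 108 without IMA1ox +Fe flg22 1 or 3, 390 with DESeq2 and 320 in a fit of those 12 libraries alone, which ended the calls of AT3G27400, AT1G03820 and NRT1.8, and that of AT1G03820 was lost with no filter on low counts or with replicate number as a block. ARD3 had 2.66 and FMO1 1.92 without WT -Fe 2, PER5 5.90 without IMA1ox -Fe 1, DIN11 3.74 without IMA1ox -Fe flg22 1, and AT3G27400 3.71 without WT +Fe flg22 3.

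**Figure D4:**
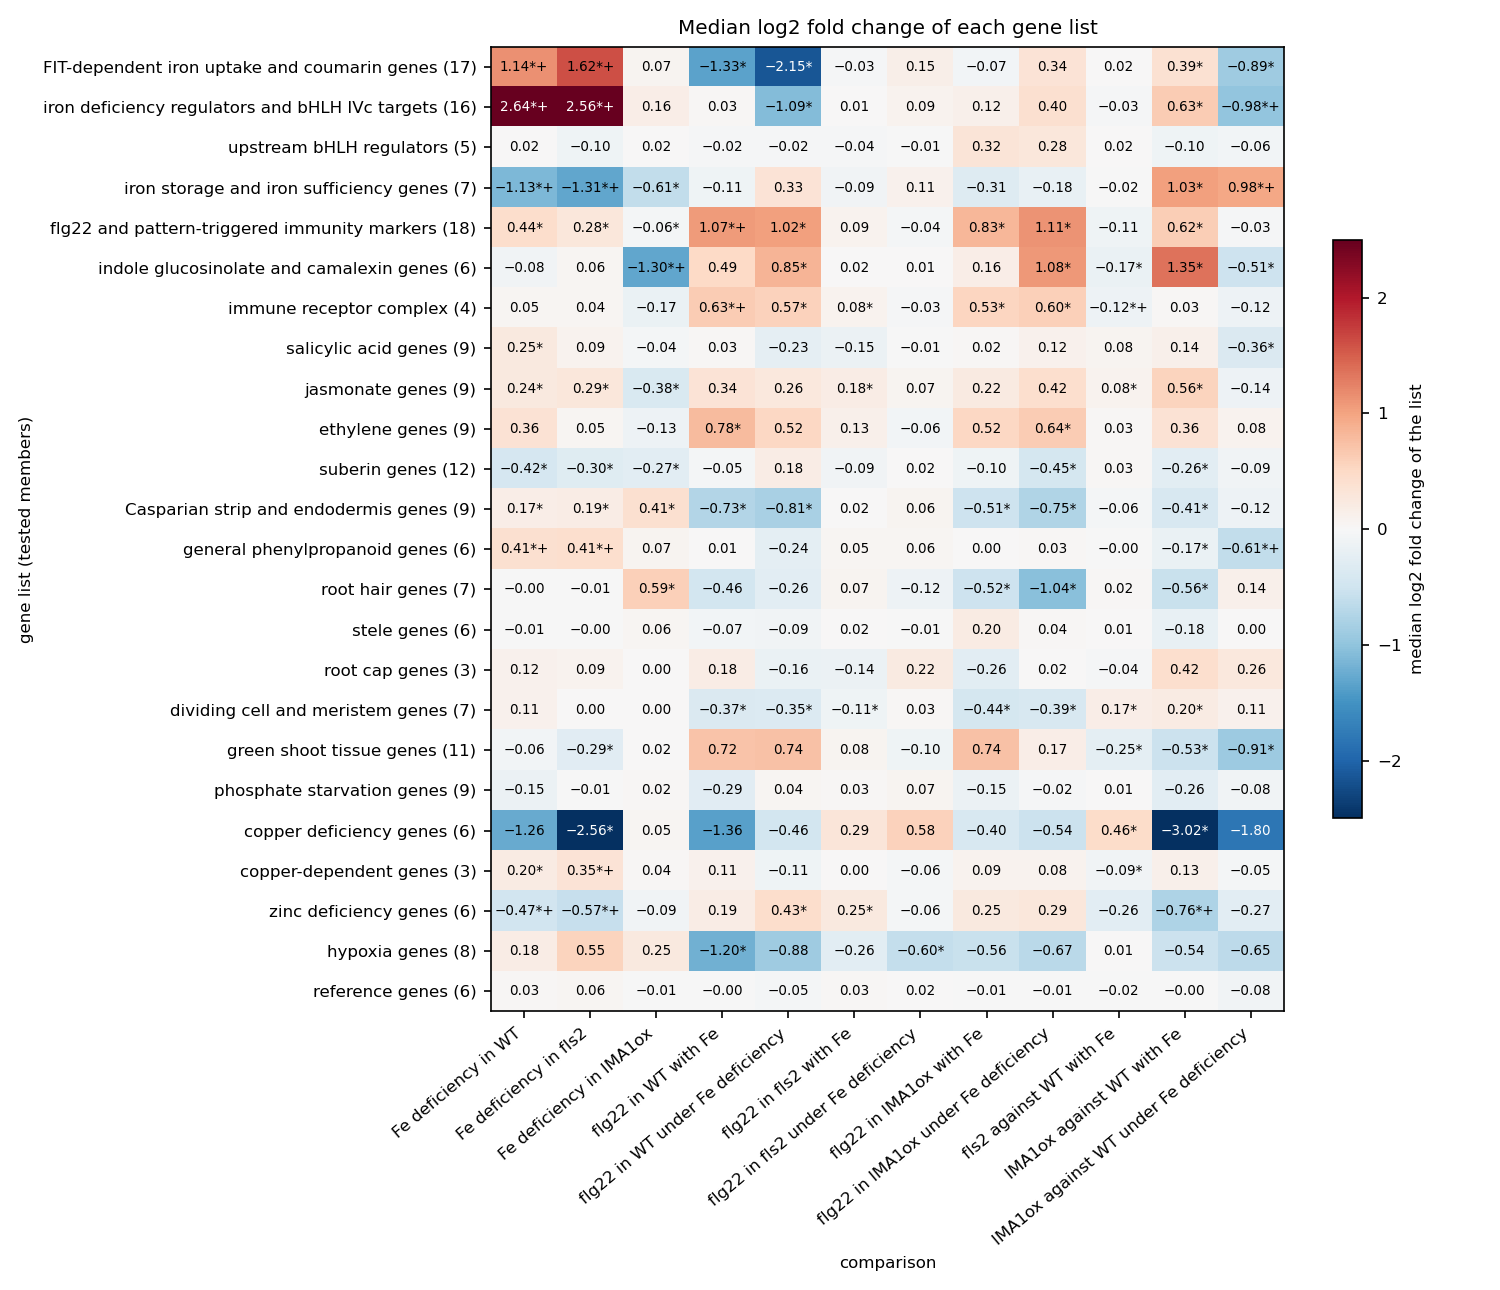
Median log2 fold change of each of the 24 gene lists (vertical axis) in each comparison (horizontal axis), with colour for the median and * for a camera adjusted p under 0.05, + where the call also held with an estimated correlation. The Fe deficiency regulators had a median of 2.64 with Fe deficiency in WT and -1.09 with flg22 in Fe-deficient WT.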

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

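All tests of explanations and all counts of sample splits in this part were chosen after the results were seen. The differences of effects between genotypes or Fe supplies in the last 4 paragraphs are given because they passed the test of the difference itself. Others that moved over 1.5-fold without 1 library are given with the comparisons.

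Raised Fe-responsive genes were lower with flg22 in Fe-deficient WT, 54 of 62 with a median of -1.37. High values in untreated Fe-deficient WT are not the whole source. Without it, 51 of the 62 were lower in flg22-treated WT than in treated fls2 (median -1.35). Loss of root hair RNA would move root hair genes as far, and their median was -0.26 with an SD of 0.44. Fe brought in with flg22 would act in fls2 too, where the raised genes' median was 0.14. Of the 62, 50 had a higher and 2 a lower response in fls2 than in WT, so the pattern depended on FLS2. Other cell types stay open.

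Fe deficiency raised 1 of these 62 genes in IMA1ox. Labels that do not follow the treatment are argued against by the Fe storage genes, of which 3 of 7 fell. Genes already at the level of Fe-deficient WT would not differ from it, and 46 of the 62 were lower in IMA1ox than in WT under Fe deficiency. Changed Fe status or feedback from IMA1 expression may account for the pattern and was not tested.

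Indole glucosinolate and camalexin genes were lower with Fe deficiency in IMA1ox, 5 of 6 with a median of -1.30. A single library does not carry the pattern, as at least 3 of 6 fell with any 1 library left out. Mixing of flg22-treated IMA1ox material into the untreated Fe-sufficient libraries, as the whole source, would need a share of at least 0.440 for each gene that fell, which lets no gene rise with flg22 by over 1.19. In IMA1ox with Fe, 3 of 18 immunity markers and 53 of all tested genes rose by more than 2 standard errors above that limit. The condition of the Fe-sufficient IMA1ox seedlings may contribute and was not tested.

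For pairs of groups, 3 against 3 libraries make 10 splits, too few for a share under 0.05. In 1 of 10 splits, the real one, the count was as large for Fe deficiency in WT (1216, highest other 1), flg22 in WT without Fe (7118, 11) and with Fe (8170, 3), Fe deficiency in fls2 (431, 0), fls2 against WT (4, 3), IMA1ox against WT with Fe (3404, 1) and without (2423, 2), Fe deficiency in IMA1ox (873, 0), flg22 in IMA1ox without Fe (9262, 450) and with Fe (8842, 0). This also held for Fe-responsive genes with flg22 in Fe-deficient WT (54, 0) and IMA1ox (20, 2) and in IMA1ox against WT (29, 0). For flg22 in fls2, all 10 splits gave 0 with and without Fe. For differences of differences, 25 splits were counted. As large was 1 split, the real one, for the fls2 and WT difference in flg22 under Fe deficiency (4318, highest other 2848), and 5 splits for the difference by Fe in WT (50, 7711), 2 for the fls2 and WT difference in flg22 with Fe (4113, 6522), and 2, 5 and 4 for the IMA1ox and WT differences in Fe deficiency (818, 1765) and in flg22 without Fe (585, 7664) and with Fe (176, 3627). Each of the other splits as large put a weight of at least 0.667 on an effect of treatment, Fe supply or genotype, where the real split puts 0, so they point to the structure of the samples and do not decide on chance. In each of these 6 comparisons, the other splits with no such weight were 1 to 8, too few for a share under 0.05, and each gave 0 genes. For the fls2 and WT difference in Fe deficiency, a real count of 0 is reached by all 25 splits (highest other 509), which decides nothing.

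The flg22 response of WT differed by Fe supply in 50 genes, 10 raised Fe-responsive genes among them, and the Fe deficiency regulators had a median difference of -0.94. Log2 differences were 1.33 for GPAT7, 1.3 for UMAMIT29, 1.25 for scpl5, -3.29 for PER5, -1.61 for HMA3, -1.24 for ZIF1, -1.0 for IREG2 and -0.88 for BTS.

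The flg22 response differed between fls2 and WT in 4318 genes under Fe deficiency, by 6.90 for AGP30, 4.97 for AT3G06460, 4.72 for AT3G19430, -7.66 for AT5G38930, -6.72 for AT2G43620, -6.64 for AT2G41810, 2.84 for IRT1, 3.12 for FRO2, 1.76 for IMA3, 1.85 for FIT, 1.53 for bHLH39 and -6.51 for FRK1. With Fe it differed in 4113 genes, by 5.52 for AGP30, 5.02 for AT5G46900, 4.22 for AT3G06460, -8.85 for GSTU12 (-11.00 without WT +Fe 1), -7.54 for AT2G43620, -7.45 for AT2G41810 (-5.26 without fls2 +Fe 1) and -5.62 for FRK1 (-4.45 without fls2 +Fe 1).

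The response to Fe deficiency differed between IMA1ox and WT in 818 genes, 44 raised Fe-responsive genes among them, with medians of -2.23 for the Fe deficiency regulators (-1.81 without IMA1) and -1.57 for indole glucosinolate and camalexin genes. Differences were 4.2 for AT5G33355, 3.4 for G3Pp2, 2.72 for AT1G34047, -6.11 for AT1G26380, -3.54 for bHLH100, -2.88 for bHLH101, -2.86 for bHLH39, -2.35 for MYB10, -7.20 for PER5, -4.0 for PER4 and -2.64 for CYP81F2. CYP82C2 had -11.19 (-8.63 to -13.00 with 1 library left out) and GLIP1 -7.45 (-6.84 to -9.18). These fitted values rest on a group with at most 3 counts and are no bound.

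The flg22 response differed between IMA1ox and WT under Fe deficiency in 585 genes, 36 raised Fe-responsive genes among them, with medians of 2.06 for FIT-dependent genes and 1.45 for the Fe deficiency regulators (1.54 without IMA1). Differences were 5.29 for ARD3 (2.66 without WT -Fe 2), 5.18 for PER5, 4.56 for DIN11, -4.96 for AT2G41810, -1.63 for KIN1, -1.49 for RSL2, 2.76 for MYB10, 2.29 for bHLH38, 2.17 for bHLH39, -0.97 for EXPA7, 2.75 for FMO1 (1.92 without WT -Fe 2) and -0.81 for GPAT5. With Fe, 176 genes differed, of which 2 raised Fe-responsive genes had a lower and 1 a higher response (median of the 62 genes 0.27), with 3.03 for AT3G27400, 2.66 for NIA1, 2.19 for AT1G03820, -7.22 for AT2G41810, -3.51 for NRT1.8 and -3.05 for GSTF6.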

How the results depend on the processing

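The 2 libraries left out together, replicate 3 of Fe-deficient WT and replicate 1 of flg22-treated Fe-deficient IMA1ox, and the lists without IMA1 or FLS2 were chosen after the data were seen, and all other alternatives before. Named genes kept their direction and side of the test in 2529 values under other settings, 98 lost and 23 gained the call and 2 reversed. With 1 library left out, 2034 kept it, 226 lost it, 10 gained it and 4 reversed. Of 288 named calls, 60 were lost without at least 1 library and 228 were kept without any 1 library. Counts of called genes stayed within 1.5 times in 153 values under other settings and moved in 27. Except where stated, the cause of a change was not tested.

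With the compared groups alone, counts fell to 373 for Fe deficiency in WT and 19 for the difference by Fe in its flg22 response. They fell to 2 for fls2 against WT and 1004 for IMA1ox against WT under Fe deficiency. They rose to 9 for flg22 in Fe-deficient fls2 and 1379 for Fe deficiency in IMA1ox. The IMA1ox and WT difference in flg22 fell to 163 without Fe and rose to 320 with Fe. DESeq2 gave 129 for the difference by Fe in WT, 11 for fls2 against WT and 390 for the IMA1ox and WT difference in the flg22 response with Fe. Without the 2 libraries, the difference by Fe in WT had 89 genes. With at least a 2-fold change, a stricter criterion, counts were 159 for Fe deficiency, 1044 and 1165 for flg22 without and with Fe and 14 for their difference in WT, 84 for Fe deficiency in fls2, 819 and 851 for the fls2 and WT difference in the flg22 response without and with Fe, 425 and 267 for IMA1ox against WT with and without Fe, 251 for Fe deficiency and 1270 and 702 for flg22 without and with Fe in IMA1ox, and 312, 146 and 78 for the IMA1ox and WT differences in Fe deficiency and in flg22 without and with Fe.

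With 1 library left out, counts ran from 711 to 1150 for Fe deficiency in WT, 5502 to 7309 and 5968 to 8573 for flg22 in WT without and with Fe, 21 to 58 for their difference, 255 to 338 for Fe deficiency in fls2, 2 to 5 for fls2 against WT, 3116 to 4833 and 2552 to 5218 for the fls2 and WT difference in flg22 without and with Fe, 2143 to 2777 and 1565 to 2174 for IMA1ox against WT with and without Fe, 470 to 672 for Fe deficiency in IMA1ox, 6250 to 9348 and 7048 to 8627 for flg22 in IMA1ox without and with Fe, and 531 to 765, 319 to 703 and 49 to 144 for the IMA1ox and WT differences in Fe deficiency and in flg22 without and with Fe. In flg22-treated fls2 and in the fls2 and WT difference in Fe deficiency every such count was 0.

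Among Fe-responsive genes, raised genes that fell with flg22 in Fe-deficient WT numbered 49 to 55 with 1 library left out, 30 with the compared groups alone, 75 of the 132 chosen in WT and 155 of the 234 chosen with no fold minimum. Those that rose numbered 2 to 3, 1 with limma-trend, 1 with the compared groups alone, 21 of the 132 chosen in WT and 14 of the 234 with no fold minimum. With flg22 in Fe-deficient IMA1ox, 2 to 6 fell and 12 to 19 rose with 1 library left out. There, 2 fell with the stricter filter or the compared groups alone. Of the 132 chosen in WT, 7 fell and 67 rose, and of the 234 with no fold minimum, 26 fell and 82 rose. In IMA1ox against WT with Fe, 0 to 3 were lower and 18 to 34 higher with 1 library left out, 1 was lower with no filter on low counts, 13 were lower and 61 higher of the 234 with no fold minimum, and 50 were higher of the 132 chosen in WT.

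With an estimated correlation, lists past the test numbered 5 for Fe deficiency, 0 and 2 for flg22 without and with Fe and 1 for their difference in WT, 6 for Fe deficiency in fls2, 0 and 0 for flg22 in fls2 and 1 for fls2 against WT, 0 for the fls2 and WT difference in Fe deficiency and 0 and 0 in flg22, 1 and 3 for IMA1ox against WT with and without Fe, 1 for Fe deficiency and 0 and 0 for flg22 in IMA1ox, and 2, 2 and 0 for the IMA1ox and WT differences in Fe deficiency and in flg22 without and with Fe. With the preset correlation, 11 lists passed for Fe deficiency in WT and 8 for flg22 in Fe-deficient WT. With FLS2, the mutated gene, left out of its list, 2 lists passed for fls2 against WT, as against 7 with it. With an estimated correlation, 1 and 2 lists then passed for the fls2 and WT difference in flg22 without and with Fe, and the other 3 immune receptor genes were lower in both (adjusted p = 0.0286 and 0.0482). By library totals alone, 1 list passed for the IMA1ox and WT difference in flg22 with Fe.

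With replicate number as a replicate block, 65 genes passed for the difference by Fe in the flg22 response of WT, 4 lists passed for fls2 against WT, and 1 raised Fe-responsive gene was lower in IMA1ox than in WT with Fe. The mean correlation of residuals was 0.0193 between libraries with the same number and -0.00962 between those with different numbers, so the numbers were not treated as pairs.

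IRT1 reversed in the difference by Fe in the flg22 response of WT with limma-trend (0.62) and without replicate 3 of flg22-treated Fe-sufficient WT, with a range of -0.98 to 2.08 over single libraries left out. FRO2 reversed there without the same library, with a range of -1.66 to 1.77. FRO2 also reversed for Fe deficiency in IMA1ox without replicate 1 of Fe-deficient IMA1ox (range -0.086 to 0.19). For flg22 in Fe-deficient IMA1ox it reversed without the 2 libraries (-0.18) and without replicate 1 of flg22-treated Fe-deficient IMA1ox (range -0.18 to 0.55). None of these IRT1 and FRO2 values passed the test as reported.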

Other observations

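The counts of shared genes and the choice of IMA1 and of the lists given here were made after the results were seen. IMA1 reads rose with flg22 in IMA1ox, by 0.51 ± 0.16 under Fe deficiency and 0.40 ± 0.16 with Fe (adjusted p = 0.0453), and include the transgene driven by the UBQ10 promoter. With 1 library left out, IMA1 (IMA1ox +Fe 1, 2 or 3, IMA1ox +Fe flg22 1 or 3, adjusted p from 0.0720 to 0.121) lost the call. Over other settings the adjusted p of the rise with Fe ran from 0.000369, with the compared groups alone, to 0.110, with DESeq2, and 5 settings ended the call. The flg22 responses of WT shared 2758 genes higher and 2513 lower with and without Fe, where 770 and 661 are expected by chance.

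Among suberin genes, 8 of 12 fell (9 adjusted over the list alone) with flg22 in Fe-deficient IMA1ox (camera adjusted p = 0.0134, adjusted p = 0.505 with an estimated correlation). Dividing cell genes responded to flg22 in Fe-deficient WT, where 4 of 7 fell (5 adjusted over the list alone) (camera adjusted p = 0.0102, adjusted p = 0.246 with an estimated correlation). The 2 libraries that stood apart most from their replicates were replicate 1 of flg22-treated Fe-deficient IMA1ox (chi-square per degree of freedom 35.5 and 25.1 against the others) and replicate 3 of Fe-deficient WT (26.2 and 17.6).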
